A study of Mus musculus with 8 samples.

How the data were processed

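Liver RNA from 8 adult male mouse samples was analysed, 4 labelled as loxP-flanked controls and 4 as liver-specific Zfp36l1 knockouts. Per the labels' protocols, total RNA was extracted with the illustra QuickPrep mRNA Purification kit and libraries were made with the NEBNext Ultra II RNA kit. The authors deposited 1 table of raw counts per gene symbol, with 25239 genes and 1 column per library, and columns were matched to samples by the library name in the sample descriptions. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, the annotation, the strand setting and their versions are not given in the sources used here. The deposited gene lengths, per the file headers a separate column of bases per gene, were used only to match genes on length.

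Total counts ranged from 104842873 to 140582588 per library, and 3 counts in a library correspond to 0.0213 to 0.0286 CPM. Floors of this kind cover counting error only. In each library 67.4% to 70.8% of the values from 1 to 20 were even, against 49% to 50.9% of high values, as when both mates of a read pair are counted, and counts divided by 2 were fitted as an alternative chosen after seeing the data. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt are listed at 0 in all 8 libraries and are not among the 6 tested members of the erythrocyte list. Xist had 4 to 30 counts per library, while Ddx3y had 10209 to 15440, in keeping with the male label. Chi-square statistics between libraries of 1 group were 4.8 to 13.3 per gene. Separate preparations from 1 mouse would exceed sampling noise as well, so each library was counted as a replicate on the labels alone. The first principal component of log2 CPM held 32.2% of the variance, with control libraries at −39.3 to 1.5 and knockout libraries at 7 to 39.8.

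Groups came from the sample labels. Genes were filtered with filterByExpr, which kept 14861 genes with 99.99% of counts and left out 10378. Counts were normalized with TMM and tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest), which left 6 residual degrees of freedom before moderation, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.204. Standard errors were computed as the absolute log2 fold change divided by the square root of F and are approximate. The targeted gene was also tested with an exact two-sided permutation test of log2 CPM. 40 gene lists with 1096 member entries, of which 1088 are in the table and 1022 were tested, were compared with camera from limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, using log2 CPM with a prior count of 2. With an estimated correlation 0 of the 40 lists passed (lowest adjusted p = 0.26), against 16 with the preset one. Fry's directional test passed for 4 of those 16 lists and had adjusted p = 0.054 to 0.47 for the others, and its mixed test passed for 28 of the 40. The mixed test asks whether members changed in either direction, not whether a list changed more than other genes.

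The design, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Named genes are Zfp36l1, the 12 largest fold increases and 12 largest decreases among genes past the threshold with at least 1 CPM in the higher group and groups that do not overlap (leaving out predicted, Rik and pseudogene symbols), up to 4 members of each list with the lowest adjusted p and all changed members where 5 or fewer changed, a fixed set of genes, and the 5 lowest adjusted p-values in each direction. Some genes that the rule names are not reported here. Scd1, Fasn, 9430078K24Rik and 2310015A10Rik were added after their values were seen. Of 112 named genes checked against the annotation, 17 overlap another gene of the table and 15 have such a partner on the opposite strand, among them Gprc5b, Cidea, Tctex1d4, Elovl6, Me1, Acaca, Mttp, Sult1a1, G6pdx and Rtp4. Reads of such partners, and of close gene families, cannot be separated here.

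Positions and 3′ UTR sequences were taken from GENCODE M21 for GRCm38, the assembly of mm10, by symbol, which matched 24366 genes of the table and 14614 tested genes. Of these 13699 tested genes had an annotated 3′ UTR of at least 20 bases. Genes with and without UAUUUAU were compared within 10 bins of 3′ UTR length and 10 of mean expression, with 100000 shuffles of the motif within bins for the main value and 2000 for its alternatives.

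Both groups carry replicate numbers 1 to 4, and the labels do not say that a number marks a shared litter, batch or day. After subtraction of the group means, same-numbered libraries correlated at 0.17, 0.39, 0.31 and 0.40 over genes, and in both groups all 4 libraries were matched best by their own number. The pairing is therefore a property of the data. The replicate number was fitted as a block, and its values stand beside the list counts and the calls that it changes.

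The alternatives were DESeq2 size factors, total counts alone, no count filter, a stricter filter of 1 CPM in 4 libraries, DESeq2's Wald test, limma with quality weights, the replicate block, removal of the 10 most abundant genes, a 1.5-fold minimum, other motifs, and each library left out in turn. Chosen after seeing the data were the halved counts, the neutrophil list score as a covariate, and total counts alone in the motif test. On simulated counts for the 14861 genes with 4 libraries per group, the test recovered 39.6% of genes changed 1.5-fold, 64% of those changed 2-fold, 92% at 4-fold and 93.2% at 8-fold over 5 runs, and 6% of calls were unchanged genes. The list test found 20 of 20 shifted lists and 0 of 40 unshifted ones. Its simulated genes varied independently, whereas estimated correlations within lists reached 0.68 for proliferation and 0.75 for neutrophil genes. The simulation therefore does not check the preset correlation of 0.01. The motif test returned 0.099 for a shift of 0.1 and −0.013 for none, with random labels on shuffled fold changes, which carry no link to 3′ UTR length or AU content. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.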

Results

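RNA was sequenced from the livers of adult male mice in 2 groups of 4 libraries. Control mice carried loxP-flanked alleles of Zfp36l1, and knockout mice carried the same alleles with a Cre recombinase transgene under the albumin promoter, which is active in hepatocytes. ZFP36L1 is a zinc finger protein that binds AU-rich elements in the 3′ untranslated regions (UTRs) of mRNAs and promotes their decay. The series title places the comparison in a study of senescence of liver cells and of how the liver recovers when alcohol has made it fail, and the labels of these 8 libraries name no alcohol treatment. Total gene counts were 104842873, 120526569, 132017092 and 119468708 in control libraries 1 to 4 and 134403656, 120200618, 140582588 and 138620593 in knockout libraries 1 to 4. The labels number the libraries without saying that each came from its own mouse, so p-values measure the spread between these libraries. Unless another test is named, adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14861 genes, fold changes are log2 values of knockout over control with their standard error (SE), and levels are TMM-normalised library-scaled counts (CPM) as mean ± SD with n = 4 per group.

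The first comparison asked whether the targeted transcript was lower in the libraries labelled knockout. Zfp36l1 (ENSMUSG00000021127.7, chromosome 12, 80107754 to 80113013, minus strand, mm10) had 263.4, 236.6, 323.5 and 212.1 CPM in the control libraries. The knockout libraries had 76.9, 57.9, 67.2 and 58.3 CPM. The group means were 259 ± 47.9 and 65.1 ± 8.97, so the knockout livers held 25.1% of the control level. The log2 fold change was −1.99 (SE 0.15, adjusted p = 0.000309), and an exact two-sided permutation test over the 70 assignments of the libraries gave p = 0.0286, the smallest it can give. That test exchanges libraries freely across replicate numbers, and swaps within same-numbered pairs alone are too few for a p under 0.05. Counts per gene sum over exons and cell types, so the remaining signal was not assigned to cells with an intact gene or to undeleted exons. The Cre transgene is named for the knockout libraries and not for the controls, so its presence and the deletion differ together between the groups.

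**Figure D1:**
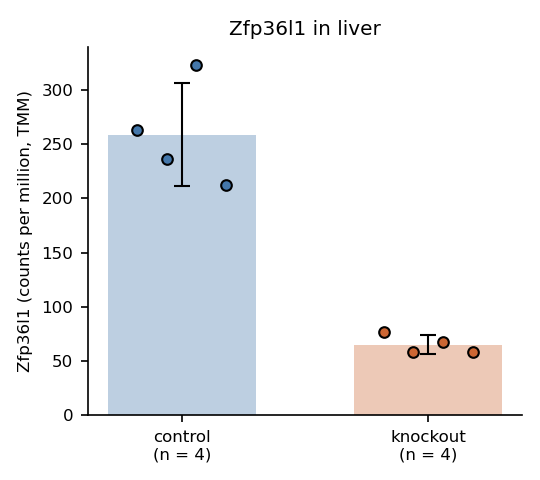
Zfp36l1 in CPM (TMM normalization) in each liver library (points), with group means (bars) and SD (error bars), n = 4 per group. All 4 knockout libraries lie between 57.9 and 76.9, below the lowest control library at 212.1.

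The main comparison asked which transcripts differed between knockout and control livers. At adjusted p under 0.05, 801 of the 14861 tested genes (5.39%) changed, 521 higher and 280 lower in the knockout. A change of at least 2-fold was found for 136 of the higher and 37 of the lower genes. The groups did not overlap for 796 of the 801 genes, and for 2245 (15.1%) of all tested genes where chance gives 2.9%. The 10 most abundant genes took 14.51% to 16.43% of counts in the control libraries and 18.92% to 20.86% in the knockout libraries, led by Alb and by Scd1, whose share was 2.3 ± 0.73% and 4.69 ± 0.5%. Scaling by total counts alone moved the median log2 fold change of all genes by −0.113 and gave 392 higher and 1338 lower genes. The 801 genes kept their direction there, so the scaling changed which genes passed and the balance of calls. The number of changed genes was 303 without control replicate 1, 396 without control replicate 2, 256 without knockout replicate 1, 394 without knockout replicate 2 and 211 without knockout replicate 3.

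**Figure D2:**
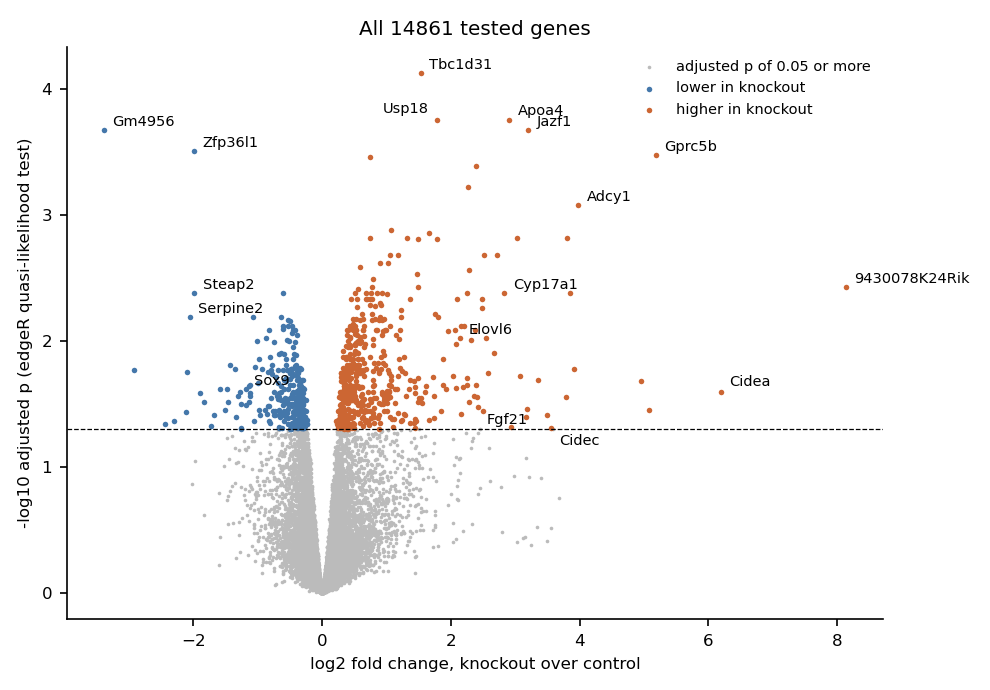
Each point is 1 of 14861 tested genes, with log2 fold change of knockout over control on the horizontal axis and −log10 of the adjusted p from edgeR's quasi-likelihood test on the vertical axis, where the dashed line marks 0.05. Orange points are the 521 higher and blue points the 280 lower genes under TMM scaling (392 and 1338 under total counts alone), and the position of 9430078K24Rik, at 0 in all control libraries, depends on the prior count.

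Genes with the largest increases included several that were close to silent in control livers. Gprc5b, an orphan G protein-coupled receptor gene (chromosome 7, 118972047 to 118995211), went from 0.933 ± 0.283 to 33.9 ± 11.9 CPM (log2 fold change 5.19, SE 0.34, adjusted p = 0.000334). Adcy1, which encodes an adenylate cyclase, went from 1.74 ± 0.617 to 27.6 ± 7.44 CPM (3.98, SE 0.31, adjusted p = 0.000836). Jazf1, a zinc finger gene, went from 0.688 ± 0.211 to 6.32 ± 0.779 CPM (3.2, SE 0.22, adjusted p = 0.000213), and the adaptor gene Shc2 from 0.298 ± 0.141 to 4.19 ± 1.42 CPM (3.81, SE 0.36, adjusted p = 0.00151). Insyn1 and the steroid dehydrogenase gene Akr1c18 rose by log2 values of 3.85 and 3.03. These 6 genes kept adjusted p under 0.05 without any single library. Apoa4, an apolipoprotein gene (chromosome 9, 46240696 to 46243459), rose from 145 ± 19.9 to 1088 ± 257 CPM (2.91, SE 0.18, adjusted p = 0.000175). Tbc1d31 had the lowest adjusted p of all genes (7.46e-05) and rose from 10.1 ± 0.977 to 29.5 ± 0.600 CPM. Gprc5b overlaps Iqck on the opposite strand, and without a stated strand setting reads of such partners cannot be told apart.

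Other large increases varied more between the knockout libraries. Cidea and Cidec encode lipid droplet proteins. Cidea rose from 0.0997 ± 0.0962 to 7.09 ± 7.49 CPM (log2 fold change 6.20, SE 1.12, adjusted p = 0.0255), and Cidec from 3.42 ± 1.07 to 40.1 ± 41.4 CPM (3.55, SE 0.80, adjusted p = 0.049). Ppp1r3g, a glycogen-targeting phosphatase subunit gene, rose by 3.19 (SE 0.65, adjusted p = 0.0348) and Ly6d by 3.49 (SE 0.76, adjusted p = 0.0383). With the replicate number as a block the adjusted p was 0.0877 for Cidea, 0.178 for Cidec, 0.114 for Ppp1r3g and 0.117 for Ly6d. Tctex1d4 rose by 5.09 (adjusted p = 0.0353) and Gldn by 4.95 (adjusted p = 0.0209). Of the 8 fits that each left out 1 library, the call was lost in 3 for Cidea, 4 for Gldn, 6 for Tctex1d4, Ppp1r3g and Ly6d and 7 for Cidec. Limma with quality weights ended the calls of Cidea, Cidec, Ppp1r3g and Tctex1d4. Without the count filter those of Cidec, Ppp1r3g, Ly6d and Tctex1d4 were lost. The lowest log2 fold change in any setting was 5.18 for Cidea, 2.57 for Cidec and 3.39 for Tctex1d4.

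Among genes that fell, Gm4956, an annotated transcribed pseudogene on chromosome 1, went from 9.15 ± 2.58 to 0.868 ± 0.176 CPM (log2 fold change −3.39, SE 0.23, adjusted p = 0.000213), with the reservation that counting may have split its reads with related genes. Serpine2, a secreted protease inhibitor gene, fell from 3.83 ± 1.22 to 0.922 ± 0.256 CPM (−2.05, SE 0.28, adjusted p = 0.00646), and the metalloreductase gene Steap2 from 13.2 ± 4.74 to 3.35 ± 0.605 CPM (−1.98, SE 0.24, adjusted p = 0.00418). Sox9, a transcription factor gene of bile duct cells, fell from 11.7 ± 1.68 to 5.17 ± 1.98 CPM (−1.18, SE 0.23, adjusted p = 0.0242). Other genes with large decreases were Pclo (−2.12), Jph1 (−1.90), Nap1l3 (−1.43), Atp6v0d2 (−1.28), Dsg1c (−1.27) and Cyp2c69. Hmgn1, a nucleosome-binding protein gene, and C730036E19Rik fell less (−0.61 and −0.64) and were among the 5 lowest adjusted p-values in that direction. The call was lost in 1 leave-one-out fit for Nap1l3 (0.0536 without knockout replicate 3), in 4 for Jph1, 5 for Sox9 and Atp6v0d2, 6 for Pclo and Cyp2c69 and 7 for Dsg1c.

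Interferon response genes were the list with the most changed members. Of 45 tested members, 22 rose and 0 fell (33 adjusted over the list alone, 25 and 0 with the replicate block), and the median log2 fold change was 0.69. Usp18, which encodes a protease that removes the ISG15 modifier, rose from 10.6 ± 0.573 to 36.6 ± 6.19 CPM (1.79, SE 0.12, adjusted p = 0.000175). Ifi44 rose from 4.66 ± 0.694 to 14.8 ± 2.82 CPM (1.67, SE 0.16, adjusted p = 0.0014), the antiviral gene Oas1a from 2.75 ± 0.322 to 7.67 ± 1.62 CPM (1.48, SE 0.17, adjusted p = 0.0029) and Rtp4 rose by 0.90 (SE 0.12, adjusted p = 0.005). The list passed camera with a preset correlation of 0.01 (adjusted p = 1.1e-18), had adjusted p = 0.44 with an estimated correlation, and passed fry (adjusted p = 0.032, or 0.075 with the replicate block). List scores, the mean log2 CPM relative to the control mean, were −0.05 to 0.10 in the control libraries and 0.75, 0.27, 0.79 and 0.77 in knockout libraries 1 to 4.

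Genes of fatty acid synthesis and esterification were higher as a list by camera. Of 27 tested members, 11 rose and 0 fell (14 adjusted over the list alone), with a median log2 fold change of 0.59 and camera adjusted p = 4e-08 (adjusted p = 0.56 with an estimated correlation). Fry gave 0.054, or 0.14 with the replicate block. Me1, which supplies NADPH, rose from 591 ± 106 to 1376 ± 239 CPM (1.22, SE 0.16, adjusted p = 0.00645). Elovl6, a fatty acid elongase gene, rose from 189 ± 70.1 to 837 ± 266 CPM (2.15, SE 0.31, adjusted p = 0.00953), Acaca (acetyl-CoA carboxylase) by 0.95 (SE 0.13, adjusted p = 0.00667) and the desaturase gene Fads2 by 0.59 (SE 0.08, adjusted p = 0.00682). Scd1 and Fasn were chosen after their values were seen. Scd1 rose from 22177 ± 7287 to 48885 ± 5908 CPM (1.14, SE 0.23, adjusted p = 0.024), and Fasn (fatty acid synthase) from 2529 ± 1167 to 7142 ± 1231 CPM (SE 0.31, adjusted p = 0.0307, or 0.0635 with the replicate block). Leaving out 1 library ended the call in 4 of 8 fits for Scd1 and in 6 for Fasn, with adjusted p-values up to 0.0682 and 0.084.

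Lipid droplet and lipid uptake genes followed the same direction, with 8 of 22 tested members higher and 0 lower (11 higher and 1 lower adjusted over the list alone, 7 and 1 with the replicate block). The median was 0.48 and camera gave adjusted p = 3.2e-05 (adjusted p = 0.44 with an estimated correlation), while fry gave 0.033, or 0.15 with the replicate block. Besides Cidea and Cidec, Mttp, which loads lipid onto apolipoprotein B, rose from 509 ± 27.1 to 855 ± 46.5 CPM (0.75, SE 0.07, adjusted p = 0.00151). The fatty acid binding protein gene Fabp4 rose by 0.95 (SE 0.15, adjusted p = 0.012), the nuclear receptor gene Pparg by 0.88 (SE 0.16, adjusted p = 0.0178, and 0.0592 without control replicate 1) and the lipase gene Pnpla2 by 0.51 (adjusted p = 0.0228, lost in 4 leave-one-out fits). Cholesterol synthesis and uptake genes did not pass camera (adjusted p = 0.82). Of its 26 tested members 0 rose and 1 fell (3 higher and 3 lower adjusted over the list alone, 2 higher and 2 lower with the replicate block, and 0 higher and 5 lower under total counts alone). The median was −0.09 and the mean 0.03. The member that fell was Mvk (−0.67, adjusted p = 0.0358, lost in 7 leave-one-out fits).

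Genes of fasting metabolism and stress were also higher as lists by camera with the preset correlation. For gluconeogenesis and fasting, 4 of 20 tested members rose and 0 fell (6 and 1 adjusted over the list alone, 2 and 0 with the replicate block), camera adjusted p = 0.0011 (adjusted p = 0.44 with an estimated correlation), and fry gave 0.033, or 0.1 with the block. Igfbp1 rose from 72.2 ± 30.4 to 306 ± 83.2 CPM (2.08, SE 0.30, adjusted p = 0.0106, or 0.0544 with the block), and the transaminase gene Got1 by 1.03 (adjusted p = 0.0266, or 0.082 with the block). Fgf21, a hormone gene of fasting and cell stress, rose from 2.93 ± 1.89 to 15.8 ± 6.34 CPM (2.43, SE 0.49, adjusted p = 0.0335). Of 38 tested fatty acid oxidation and PPARα target genes 3 rose and 0 fell (5 and 0 adjusted over the list alone, 5 and 1 with the block, 1 and 0 under total counts alone). Camera gave adjusted p = 0.0012 (adjusted p = 0.74 with an estimated correlation), fry 0.34 and its mixed test 0.087. The 3 higher genes were Fgf21, the carnitine acyltransferase gene Crat (0.72) and Cpt1a (0.38), which controls fatty acid entry into mitochondria. Crat and Cpt1a did not pass under total counts alone. Scores of this list were −0.30 to 0.26 in the control libraries and 0.40, 0.63, 0.54 and −0.30 in knockout libraries 1 to 4, so knockout library 4 did not share the shift. For NRF2 targets and glutathione, 3 of 33 rose (6 adjusted over the list alone) and 0 fell, namely the redox genes Srxn1 (0.52) and Txnrd1 (0.32) and G6pdx (1.30) of the pentose phosphate pathway (camera adjusted p = 0.0029, and adjusted p = 0.71 with an estimated correlation). Fry gave 0.23 for this list. Scores were −0.07 to 0.05 in control and 0.25, 0.40, 0.19 and 0.04 in knockout libraries 1 to 4. For the endoplasmic reticulum stress list, 3 of 32 rose (3 adjusted over the list alone) and 0 fell, namely Fgf21 and the transcription factor genes Atf5 (0.48) and Atf3 (1.5). Its camera adjusted p was 0.017 (adjusted p = 0.71 with an estimated correlation), and 0.061 without control replicate 1, 0.23 without control replicate 3 and 0.11 without knockout replicate 2. Fry gave 0.34 and its mixed test 0.1. Scores were −0.33 to 0.31 in control and 0.11 to 0.56 in knockout libraries. Leave-one-out fits ended the calls of Fgf21, Got1 and Cpt1a in 6 of 8 cases, Crat, Txnrd1 and Atf5 in 7, Srxn1 and G6pdx in 4 and Atf3 in 8, with adjusted p-values up to 0.121. Txnrd1 and Atf5 also did not pass under total counts alone. That scaling gave 3 higher and 1 lower for gluconeogenesis and fasting, 2 and 1 for NRF2 targets and 2 and 0 for endoplasmic reticulum stress.

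**Figure D3:**
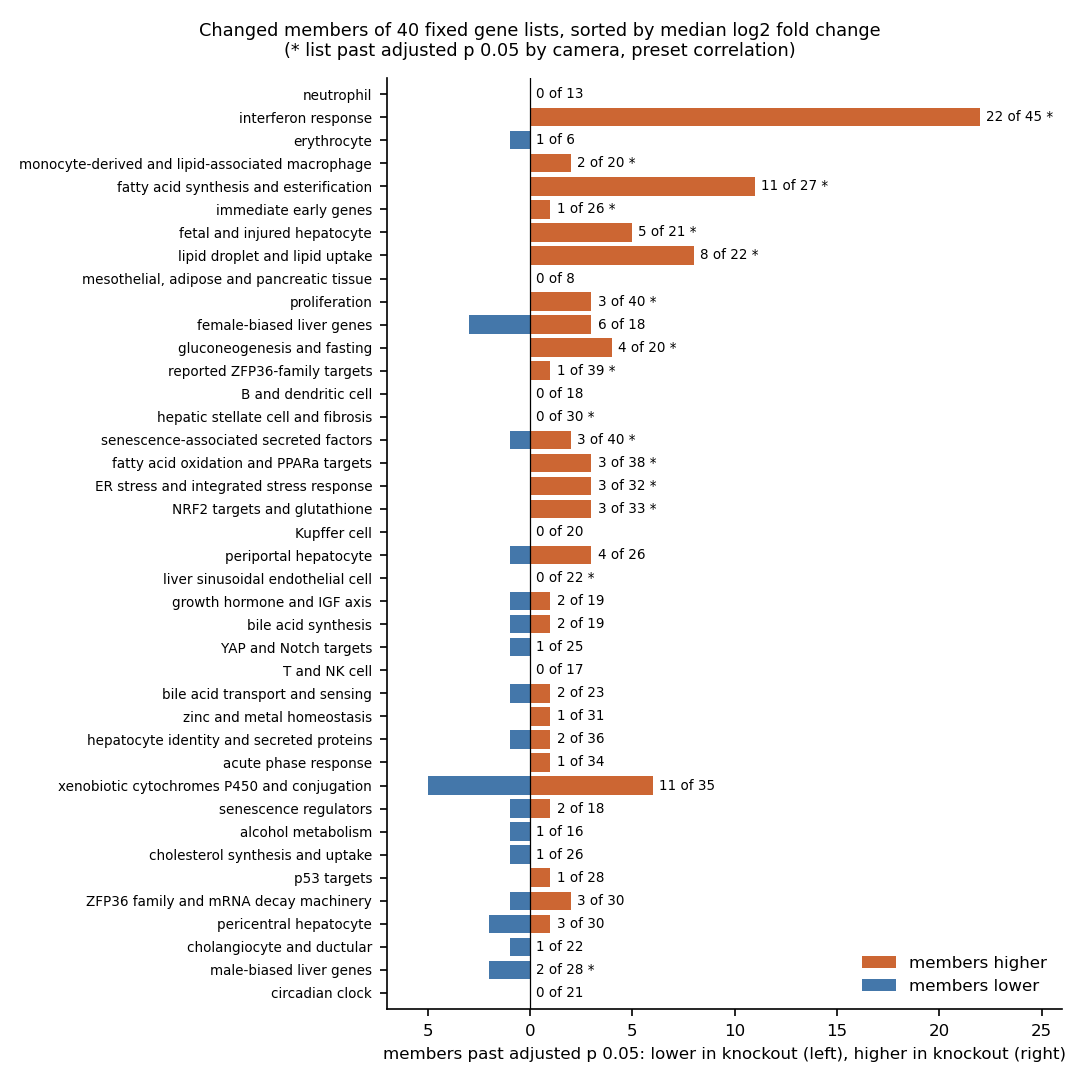
Bars give the number of tested members of each of 40 fixed gene lists that were higher (orange, right) or lower (blue, left) in the knockout at adjusted p under 0.05 by edgeR, with lists sorted by median log2 fold change. Interferon response had 22 of 45 members changed and fatty acid synthesis 11 of 27, and the medians of sinusoidal endothelial, T and NK cell, bile acid synthesis, YAP and Notch and growth hormone genes turned negative under total counts alone (between −0.1 and −0.01).

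Senescence regulators showed no shift in 1 direction as a list (camera adjusted p = 0.34). Fry's mixed test gave adjusted p = 0.0017. It counts changes in either direction without comparing a list with other genes, and 28 of the 40 lists passed it. Of 18 tested members 1 rose and 1 fell (1 and 1 adjusted over the list alone, 1 and 0 with the replicate block). The transcription factor gene Ets2 rose by 0.35 (SE 0.09, adjusted p = 0.0497) and Trp53, which encodes p53, had −0.30 (SE 0.07, adjusted p = 0.049, or 0.0679 with the block), and each call was lost in 7 leave-one-out fits. Cdkn1a, the p21 gene, had 13.2 ± 10.8 and 16.5 ± 6.24 CPM (0.32, SE 0.65, adjusted p = 0.816). Cdkn2a was not tested, with 2 to 10 counts in control and 6 to 11 in knockout libraries. Of 28 p53 targets 1 rose and 0 fell (1 and 2 adjusted over the list alone, 1 and 1 with the block; camera adjusted p = 0.47, fry's mixed test adjusted p = 1.6e-06), the ubiquitin ligase gene Mdm2 from 34.2 ± 0.996 to 44.9 ± 1.61 CPM (0.39, SE 0.06, adjusted p = 0.0082). Among 40 senescence-associated secreted factors, 2 rose and 1 fell (4 and 1 adjusted over the list alone, 3 and 2 with the block). Inhba, an activin subunit gene, rose by 0.59 (SE 0.09, adjusted p = 0.01) and the protease gene Mmp12 by 2.28 (adjusted p = 0.0307, or 0.0565 with the block, lost in 5 leave-one-out fits), and Serpine2 fell. That list had camera adjusted p = 0.034 (adjusted p = 0.71 with an estimated correlation), but 0.49 with a stricter count filter, 0.066 without control replicate 2, 0.12 without control replicate 3, 0.053 without knockout replicate 3 and 0.12 without knockout replicate 4. Gdf15 had 5.29 ± 1.99 and 6.10 ± 1.25 CPM (adjusted p = 0.7).

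Proliferation genes had a log2 fold change above 0 for all 40 tested members under TMM scaling (35 under total counts alone), with a median of 0.44, while 3 rose by themselves and 0 fell (4 and 0 adjusted over the list alone, 4 and 0 with the replicate block). Those were the cell cycle regulator gene E2f1 (0.69, adjusted p = 0.0167) and the DNA replication genes Rrm2 (1.11, adjusted p = 0.042) and Mcm2 (0.71, adjusted p = 0.043, or 0.054 with the replicate block), whose calls were lost in 2, 7 and 6 leave-one-out fits. Camera gave adjusted p = 4.3e-07 (adjusted p = 0.71 with an estimated correlation). Fry gave 0.27, or 0.25 with the block, and its mixed test 0.11. Control library 4 had a list score of 1.09, against −0.48 to −0.30 in the other control libraries and 0.23 to 1.05 in the knockout libraries. Mki67 had 3.62 ± 3.47 and 5.92 ± 2.66 CPM (adjusted p = 0.552), and Ccnd1, the cyclin D1 gene, 24.4 ± 7.86 and 24.7 ± 4.89 CPM (adjusted p = 0.965).

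Reported mRNA targets of the ZFP36 family were higher as a list by camera (median 0.34, adjusted p = 0.0029, and adjusted p = 0.44 with an estimated correlation). Their scores overlapped, with 0.01, −0.1, −0.15 and 0.24 in control and 0.3, 0.47, 0.11 and 0.66 in knockout libraries 1 to 4. Of 39 tested members 1 rose, E2f1, and 0 fell (3 and 1 adjusted over the list alone, 2 and 3 with the replicate block), and fry gave 0.058, or 0.018 with the block. Vegfa had 184 ± 8.87 and 190 ± 1.35 CPM (0.04, SE 0.06, adjusted p = 0.716). Immediate early genes, which share members with those targets, had 1 member higher, Atf3, and 0 lower of 26 (5 and 1 adjusted over the list alone, 3 and 0 with the block). Camera gave adjusted p = 0.0071 (adjusted p = 0.71 with an estimated correlation) and fry 0.23. Scores of that list overlapped as well, at −0.13 to 0.17 in control and 0.13 to 0.97 in knockout libraries. Among the remaining ZFP36 family and mRNA decay genes, 2 of 30 rose and 1 fell (2 and 2 adjusted over the list alone, 0 and 2 with the block, 0 and 4 under total counts alone; camera adjusted p = 0.16). The deadenylase gene Parn fell (−0.33, adjusted p = 0.0288), and Rc3h2 and Auh rose by 0.29 and 0.40, with adjusted p = 0.0548 and 0.0551 with the block. The calls were lost in 6 leave-one-out fits for Parn and 7 for Rc3h2 and Auh. The family members Zfp36 (0.22, SE 0.23, adjusted p = 0.62) and Zfp36l2 (0.34, SE 0.15, adjusted p = 0.231) did not pass.

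The 3′ UTR was examined for UAUUUAU, the sequence that ZFP36 proteins bind. Of 13699 tested genes with an annotated 3′ UTR, 4073 held at least 1 copy. Of the genes with a copy 248 rose and 31 fell, and of the 9626 without a copy 258 rose and 227 fell. The odds of being higher among changed genes were 7.02 times as large with a copy (95% interval 4.6 to 11, two-sided Fisher's exact test p = 5.6e-26, over genes, which are not independent replicates). These odds were not matched on 3′ UTR length or expression. Under total counts alone, where most changed genes fell, the counts were 168 higher and 193 lower with a copy and 210 and 1085 without, an odds ratio of 4.49 (3.46 to 5.84). The median log2 fold change was 0.06 with a copy and −0.03 without. Matched on 3′ UTR length and expression the difference was 0.0705, and a permutation test with 100000 shuffles gave p = 1e-05, the smallest it can give. Genes with 1, 2 and 3 or more copies had medians of 0.057, 0.062 and 0.069. Relative to the median of their length and expression bin these were 0.0518, 0.0476 and 0.0587, and 6.25%, 6.17% and 5.16% of these genes were called higher. The unmatched medians rise at each step, the matched medians and the shares do not, and no test of a trend was made.

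**Figure D4:**
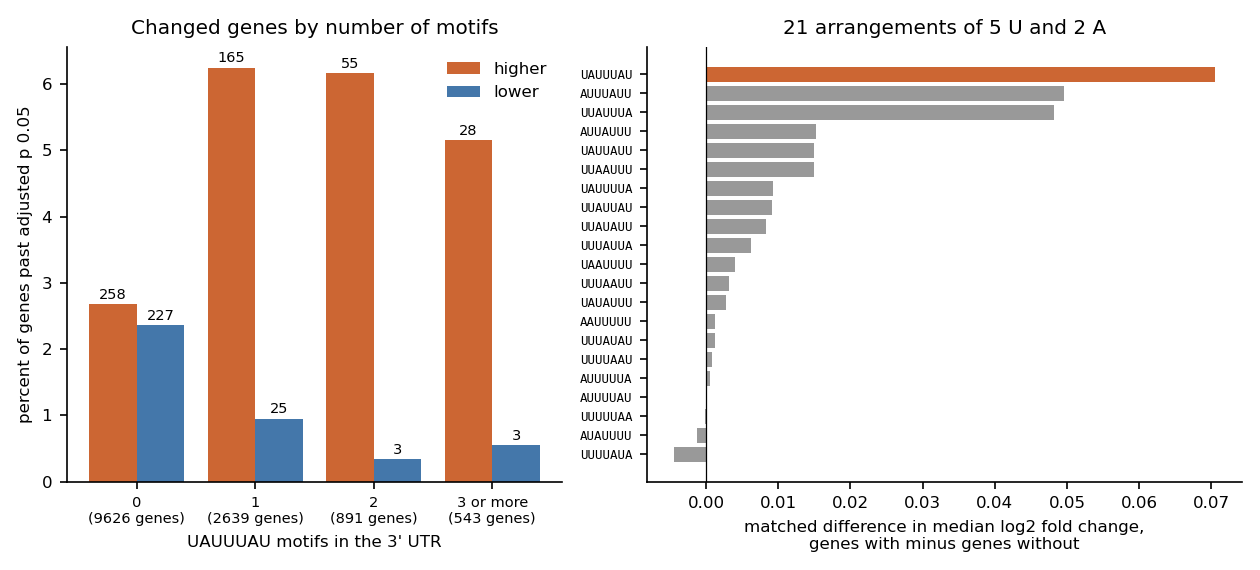
Left, percent of genes past adjusted p 0.05 in each direction (bars, with numbers of genes on top) by the number of UAUUUAU copies in the 3′ UTR, where 165 of 2639 genes with 1 copy were higher and 25 lower under TMM scaling; with at least 1 copy, total counts alone gave 168 higher and 193 lower. Right, difference in median log2 fold change between genes with and without each of the 21 arrangements of 5 U and 2 A, matched on 3′ UTR length and expression, which was 0.0705 for UAUUUAU and 0.0496 for the next.

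Bile acid genes showed no shift in 1 direction as lists. Fry's mixed test gave adjusted p = 0.0012 for synthesis and 9.9e-05 for transport and sensing. For synthesis, 1 of 19 tested members rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.73), namely the cholesterol hydroxylase gene Cyp46a1, from 1.64 ± 0.349 to 5.72 ± 1.64 CPM (1.80, SE 0.24, adjusted p = 0.00645), and Akr1c6 (−0.35, adjusted p = 0.0317). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 119 ± 59.8 and 134 ± 45.5 CPM (0.17, SE 0.41, adjusted p = 0.842). For transport and sensing, 1 of 23 rose and 1 fell (1 and 1 adjusted over the list alone, 2 and 1 with the replicate block; camera adjusted p = 0.65). The bile acid uptake transporter gene Slc10a1 rose from 565 ± 68.5 to 812 ± 60 CPM (0.52, SE 0.10, adjusted p = 0.0209, and 0.0694 without knockout replicate 3), and Fgfr4, the receptor for a bile acid-induced hormone, fell from 81.5 ± 2.89 to 66.3 ± 1.65 CPM (−0.30, SE 0.06, adjusted p = 0.0204). Leaving out 1 library ended the call in 6 fits for Akr1c6 and 4 for Fgfr4.

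Zinc and alcohol genes showed few changes by single genes. Fry's mixed test, which does not compare a list with other genes, gave adjusted p = 0.003 and 0.0033. Of 31 zinc and metal homeostasis genes 1 rose, the zinc transporter gene Slc30a9 from 60.1 ± 4.34 to 81.1 ± 3.30 CPM (0.43, SE 0.07, adjusted p = 0.0111), and 0 fell (1 and 0 adjusted over the list alone, 3 and 0 with the replicate block; camera adjusted p = 0.36, median −0.01 and mean 0.15). The metallothionein genes Mt1 (0.17, SE 0.31, adjusted p = 0.783) and Mt2 (0.33, SE 0.45, adjusted p = 0.713) did not pass. Their levels were low, with 1.87 ± 0.626 CPM in control and 2.115 ± 0.788 in knockout libraries for Mt1 and 0.49 ± 0.204 and 0.618 ± 0.381 for Mt2. Of 16 alcohol metabolism genes 0 rose and 1 fell, Adh6-ps1 (−0.74, adjusted p = 0.025, lost in 4 leave-one-out fits; 0 and 1 adjusted over the list alone; camera adjusted p = 0.45). Adh1 (0.25, SE 0.09, adjusted p = 0.137) and Cyp2e1 (−0.12, SE 0.12, adjusted p = 0.589) did not pass. Xenobiotic cytochromes P450 and conjugation genes went both ways, with 6 of 35 higher and 5 lower (6 and 10 adjusted over the list alone, 5 and 6 with the block; camera adjusted p = 0.99, median −0.06 and mean 0.07). The sulfotransferase gene Sult1a1 rose from 130 ± 17.2 to 294 ± 40 CPM (1.18, SE 0.12, adjusted p = 0.00209) and Cyp3a59 by 0.78 (SE 0.11, adjusted p = 0.00682), and Cyp2d22 fell (−0.41, adjusted p = 0.0128, lost in 2 leave-one-out fits). Reads of cytochrome genes can be shared with near-identical relatives, so their values are uncertain.

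Genes that differ between male and female livers changed in part. For male-biased genes, 0 of 28 rose and 2 fell (0 and 4 adjusted over the list alone, 1 and 5 with the replicate block), with a median of −0.25. List scores overlapped, with 0.03, 0.11, −0.55 and 0.42 in control and −0.32, −0.63, −0.77 and 0.13 in knockout libraries 1 to 4. Mup20, a major urinary protein gene, went from 4061 ± 922 to 2019 ± 201 CPM (−1.01, SE 0.16, adjusted p = 0.01), and Cyp2d9 from 1574 ± 138 to 1198 ± 109 CPM (−0.39, adjusted p = 0.0448, lost in 7 leave-one-out fits). Camera gave adjusted p = 0.043 (adjusted p = 0.71 with an estimated correlation), but 0.066 with a stricter count filter, 0.065 without control replicate 1, 0.078 without control replicate 2, 0.22 without control replicate 4 and 0.15 without knockout replicate 3. For female-biased genes, 3 of 18 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.078, 0.024 with the block, 0.017 without control replicate 3 and 0.0013 without knockout replicate 4). With an estimated correlation that list had 0.74, or 0.64 with the block, and fry with the block gave 0.23. Its scores overlapped as well, with −0.02, −0.10, 0.53 and −0.41 in control and 0.55, 0.82, 0.79 and −0.14 in knockout libraries 1 to 4. The steroid hydroxylase gene Cyp17a1 rose from 5.71 ± 1.45 to 40.7 ± 15.5 CPM (2.83, SE 0.31, adjusted p = 0.00418), Cyp2a4 by 1.88 (SE 0.31, adjusted p = 0.014) and Slc22a27 by 2.19 (adjusted p = 0.023, lost in 4 leave-one-out fits), and Atp6v0d2, Cyp2c40 and Cyp2c69 fell. Mup, Cyp2a and Cyp2c genes have close relatives, and their values are uncertain in the same way. Growth hormone and IGF axis genes showed no shift in 1 direction as a list (camera adjusted p = 0.72, fry's mixed test adjusted p = 0.00012). Of 19 members 1 was higher, Igfbp1, and 1 lower, Igfals (4 and 3 adjusted over the list alone, 2 and 1 with the block). Igfals had −0.35 and adjusted p = 0.0408, or 0.0538 with the block, and its call was lost in all 8 leave-one-out fits.

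Fetal and injured hepatocyte genes were higher, with 5 of 21 tested members up and 0 down (9 and 0 adjusted over the list alone, 5 and 1 with the replicate block) and a median of 0.51. Camera gave adjusted p = 0.0011 (adjusted p = 0.26 with an estimated correlation) and fry 0.0071. Anxa5, a phospholipid-binding protein gene, rose from 64.5 ± 8.33 to 111 ± 17.8 CPM (0.79, SE 0.13, adjusted p = 0.0108). Cd63 (0.79, adjusted p = 0.0204), Igf2bp2 (1.00, adjusted p = 0.0308), Scd2 (0.80, adjusted p = 0.0342) and Ly6d also rose, with calls lost in 5, 5, 6 and 6 leave-one-out fits. Hepatocyte identity and secreted protein genes showed no shift in 1 direction as a list (1 of 36 higher and 1 lower, 6 and 3 adjusted over the list alone, 2 and 3 with the block; camera adjusted p = 0.63, fry's mixed test adjusted p = 1.2e-05, median −0.01 and mean 0.08). Rbp4, the retinol carrier gene, rose by 0.55 (SE 0.10, adjusted p = 0.0156, and 0.0545 without knockout replicate 3), Asgr2, an asialoglycoprotein receptor gene, fell (−0.47, SE 0.07, adjusted p = 0.00754), and Alb had 0.32 (SE 0.09, adjusted p = 0.0856). Pericentral genes had 1 of 30 higher (Cyp2a5, 1.03, adjusted p = 0.025, or 0.0509 with the block) and 2 lower (Notum, −0.78, adjusted p = 0.015, and Cyp1a2, −0.46, adjusted p = 0.036), with 1 and 2 adjusted over the list alone and camera adjusted p = 0.33. Periportal genes had 3 of 26 higher (Apoa4, Hsd17b13 at 0.45 and Spp2 at 0.44) and 1 lower (Pigr, −0.61), with 4 and 3 adjusted over the list alone, 5 and 1 with the block and camera adjusted p = 0.38. Calls were lost without knockout replicate 3 for Notum (0.0519), in 6 leave-one-out fits for Cyp2a5, 7 for Cyp1a2, 4 for Hsd17b13, 5 for Spp2 and 3 for Pigr.

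Markers of other liver cell types changed little gene by gene. Monocyte-derived and lipid-associated macrophage genes were higher as a list (median 0.60, camera adjusted p = 0.00049, and adjusted p = 0.71 with an estimated correlation), with 2 of 20 members higher and 0 lower (2 and 0 adjusted over the list alone, 4 and 0 with the replicate block). These were Cd9, from 19.9 ± 1.33 to 33.4 ± 4.22 CPM (0.75, SE 0.10, adjusted p = 0.00518), and Mmp12, and fry gave 0.23, or 0.0027 with the block. Stellate cell and fibrosis genes (30 tested, 0 higher and 0 lower, also adjusted over the list alone) had a median of 0.27 and camera adjusted p = 0.017 (adjusted p = 0.74 with an estimated correlation), and 0.23 without control replicate 1, 0.26 without knockout replicate 3 and 0.055 without knockout replicate 4. Sinusoidal endothelial genes (22 tested, 0 higher and 0 lower, also adjusted over the list alone) had a median of 0.10, which was −0.01 under total counts alone, and camera adjusted p = 0.045 (adjusted p = 0.74 with an estimated correlation). Their camera adjusted p was 0.19 without control replicate 1, 0.089 without control replicate 2, 0.17 without control replicate 4, 0.14 without knockout replicate 3 and 0.41 without knockout replicate 4. With the block 1 stellate and 1 endothelial gene were higher.

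Neutrophil genes stood high in some libraries of both groups. Their scores were 0.97, −1.50, −1.64 and 2.18 in control libraries 1 to 4 and 3.83, −1.51, −1.57 and 3.23 in knockout libraries 1 to 4, with 0 of 13 genes changed (0 adjusted over the list alone) and camera adjusted p = 0.24. That value was 0.012 with the replicate block, 0.044 without control replicate 4, 0.031 without knockout replicate 2 and 0.026 without knockout replicate 3. With the block it was 0.67 with an estimated correlation, and fry gave 0.41. Kupffer cell (20 tested, camera adjusted p = 0.67, and 0.044 without knockout replicate 2), T and NK cell (17, 0.72) and B and dendritic cell genes (18, 0.22, and 0.043 without control replicate 1 and 0.038 without knockout replicate 2) had 0 members changed, also adjusted over the list alone (1 T and NK cell gene was higher and 1 lower with the block), although 3190 of all genes had an unadjusted p under 0.05 in edgeR's test. The deposited counts hold 22 of the 25 T and NK cell list members and 18 of the 21 B and dendritic ones. Trac, Trbc1, Ighm and Igkc are among those absent. The cholangiocyte list had 1 of 22 members lower, Sox9, and 0 higher (1 adjusted over the list alone; camera adjusted p = 0.24). The erythrocyte list had 1 of 6 lower, the transcription factor gene Klf1 (−0.84, adjusted p = 0.018, lost in 2 leave-one-out fits), and 0 higher (1 adjusted over the list alone, 2 higher and 1 lower with the block; camera adjusted p = 0.65). Mesothelial, adipose and pancreatic genes had 0 of 8 changed (0 adjusted over the list alone; camera adjusted p = 0.29, and 0.0065 without knockout replicate 1).

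Among other hepatic programs, acute phase genes had 1 of 34 higher, Serpina3m (0.28, adjusted p = 0.0363, or 0.0512 with the replicate block, lost in 7 leave-one-out fits), and 0 lower (0 and 0 adjusted over the list alone, 2 and 4 with the block; camera adjusted p = 0.91, and 0.042 without knockout replicate 4). Their scores were 0.87 and 0.90 in the libraries numbered 4 and −0.58 and −0.57 in those numbered 3. YAP and Notch targets had 1 of 25 lower, Sox9, and 0 higher (1 adjusted over the list alone, 0 higher and 2 lower with the block; camera adjusted p = 0.63). Circadian clock genes had 0 of 21 changed (0 adjusted over the list alone, 1 lower with the block) with a median of −0.30 and camera adjusted p = 0.45. Under total counts alone lower calls outnumbered higher ones for further lists where they did not under TMM. These were senescence regulators (0 higher and 2 lower), p53 targets (1 and 2), bile acid synthesis (1 and 2), bile acid transport and sensing (1 and 3), zinc and metal homeostasis (1 and 2) and xenobiotic genes (6 and 10). The others were acute phase (0 and 1), growth hormone (1 and 3), hepatocyte identity (1 and 3) and periportal genes (3 and 4). Fry's mixed test also passed, where camera did not, for mRNA decay, cholesterol, xenobiotic, female-biased, pericentral, periportal, YAP and Notch, cholangiocyte and erythrocyte genes (adjusted p = 1.6e-06 to 0.033). It did not pass for proliferation, fatty acid oxidation, endoplasmic reticulum stress, stellate or endothelial genes (0.087 to 0.29). Nor did it for acute phase, circadian, Kupffer, neutrophil, T and NK, B and dendritic or mesothelial genes (0.37 to 0.77).

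**Figure D5:**
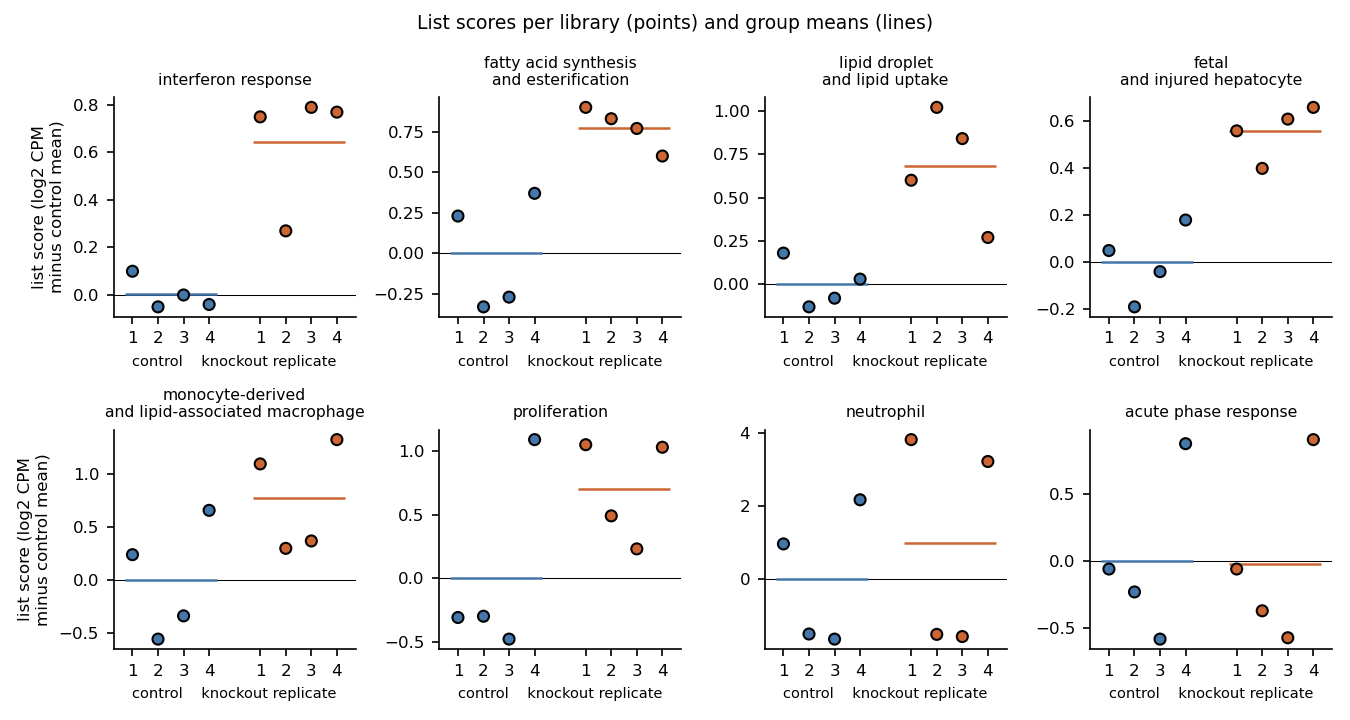
List scores per library, the mean log2 CPM of a list's members minus the control mean, for 8 lists (points are libraries by replicate number, lines are group means). Interferon scores were −0.05 to 0.10 in control and 0.27 to 0.79 in knockout libraries under TMM scaling, whereas neutrophil scores spanned −1.64 to 2.18 in control and −1.57 to 3.83 in knockout libraries.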

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

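The tests of leukocyte content and of recruited macrophages were chosen after the result was seen, as was the test without cell type and proliferation genes. A library was set apart where its gap to the nearest other library of its group was above the 95% critical value of Dixon's ratio of gap to range. This was so for 18 of 307 groups of 4, and chance at 1 in 20 gives about 15.3, so the number itself is near chance.

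In log2 CPM, Shc2 was −0.93 in control library 4 against −2.16 to −1.97 in the other controls, Ppp1r3g was −0.98 in control library 2 against 0.64 to 0.90, and Steap2 was 4.35 in control library 3 against 3.37 to 3.50. Mki67 was 3.14 in control library 4 against 0.84 to 0.98, and Fgfr4 was 6.42 there against 6.32 to 6.33. Cpt1a was 8.84 in control library 3 against 8.64 in all others, Got1 was 6.68 in control library 2 against 7.17 to 7.23, and G6pdx was 5.24 in knockout library 1 against 4.12 to 4.28.

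Among list scores, control library 4 stood apart for senescence regulators (−0.15 against 0.04 to 0.07), proliferation (1.09 against −0.48 to −0.30) and pericentral genes (0.07 against −0.03 to −0.02). Control library 2 stood apart for p53 targets (−0.05 against 0.01 to 0.02) and alcohol metabolism (−0.08 against 0.02 to 0.04). Knockout library 1 had 0.05 for bile acid transport against 0.11 to 0.12, and knockout library 2 had 0.81 for gluconeogenesis and fasting against 0.48 to 0.53 and 0.27 for the interferon response against 0.75 to 0.79. The 10 most abundant genes took 14.51% of counts in control library 2 against 16.35% to 16.43%, and ribosomal protein genes took 0.63% in control library 3 against 0.74% to 0.75%.

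Of 45 interferon response genes 22 were higher in the knockout and 23 did not pass (median 0.69). The list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.44, or 0.64 with the replicate block), and fry gave 0.032, or 0.075 with the block. More leukocytes in the knockout livers would leave the interferon score near control in libraries with low leukocyte scores. Knockout libraries 2 and 3, whose Kupffer, T and NK cell and neutrophil scores lie below the control mean, had interferon scores of 0.27 and 0.79. Both lie above the highest control at 0.10. That argues against leukocyte content as the whole cause only where libraries can be compared across numbers. Knockout library 2 had a higher T and NK cell score than control library 2 (−0.41 against −0.78), a near-equal neutrophil score (−1.51 against −1.50) and a lower Kupffer score (−0.48 against −0.24). Knockout library 3 had lower T and NK cell (−0.47 against 0.13) and Kupffer scores (−0.27 against −0.01) than control library 3, with neutrophil scores of −1.57 and −1.64. The T and NK cell score lacks Trac and Trbc1, which are not in the deposited counts. A direct effect through the motif is argued against by the 37 members without UAUUUAU, whose median was 0.67, against 0.76 for the 8 with it (permutation p = 0.68). Recruited macrophages stay open, because the test rests on 1 control library (interferon score −0.04, macrophage score above knockout libraries 2 and 3) and crosses replicate numbers. Macrophage scores were 0.24, −0.56, −0.34 and 0.66 in control and 1.1, 0.3, 0.37 and 1.33 in knockout libraries 1 to 4, higher in the knockout for each number. An interferon response of the hepatocytes and one of recruited macrophages therefore cannot be told apart, and an effect of the Cre transgene was not tested.

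Genes with UAUUUAU in the 3′ UTR were higher than matched genes without it by 0.0705, as mRNAs bound by ZFP36L1 would be in its absence, in a test that could have come out the other way. A test that also matched AU content, in 10 bins, used 5 bins each of 3′ UTR length and expression. That match on length and expression is looser than the 10 bins each of the main test. Its difference was 0.0667 (permutation p = 0.0001, the smallest 10000 shuffles can give). UAUUUAU ranked first among 21 arrangements of the same bases, ahead of AUUUAUU (0.0496) and UUAUUUA (0.0482), which overlap it. These values argue against AU content. A share of the difference from other cell types or proliferation was not decided by leaving out those lists (0.0724), because they hold only 45 of the 4073 genes with the motif. A candidate explanation is therefore slower decay of motif-bearing mRNAs, found and tested on the same libraries.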

How the results depend on the processing

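The halved counts, the neutrophil covariate and the motif test under total counts alone were chosen after seeing the data. Zfp36l1 stayed between −2.11 and −1.86 and past the threshold in all settings. All of the 801 changed genes present in a setting kept their direction there. The 97 changed genes among those named kept it as well in the settings that tested them. Apart from the leave-one-out fits and the covariate, 71 of them passed in every setting that tested them, and 38 passed in all 8 leave-one-out fits. A gene that a setting left out, as the stricter filter and the removal of abundant genes did for some, was not counted as lost there. With the replicate block 1028 genes changed (653 higher, 375 lower), 688 of the 801 among them, and beyond the values printed beside results the block changed no other call of a gene named in the text or of a list.

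The number of genes changed in the knockout was 1730 with total counts alone, with 1338 genes lower in the knockout. It was 1738 with DESeq2, with 1014 genes higher in the knockout and 724 lower, and 1434 with limma (830 and 604) and 354 with a 1.5-fold minimum (256 and 98). Leaving out 1 library gave 211 to 967 changed genes, 169 to 583 higher and 42 to 384 lower. For the 1.5-fold minimum an added condition enters by construction, and total counts alone shift the median, but for DESeq2, limma and the left-out libraries the cause was not tested, and the count rose to 967 without control replicate 3. The number was 805 with DESeq2 size factors, 709 without a filter, 842 with the stricter filter, 815 without the 10 most abundant genes, 817 with halved counts and 796 with the covariate. Of the 40 lists, 16 passed camera, 0 with an estimated correlation and 4 with fry. The motif difference ranged from 0.0305 (AUUUA) to 0.0904 (without control replicate 3) and was 0.0709 under total counts alone.

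Genes that did not pass changed sign in some settings, and the cause was not tested. Ccnd1 was −0.088 with total counts alone and −0.073 with the covariate, Vegfa −0.07 with total counts alone, Mt1 −0.13 and Mt2 −0.24 with limma, and the neutrophil gene Ltf −0.37 with the covariate. Across leave-one-out fits Cdkn1a ranged from −0.006 to 0.97, Ccnd1 from −0.11 to 0.21, Cyp7a1 from −0.063 to 0.54, Mt1 from −0.06 to 0.42, Mt2 from −0.14 to 0.62 and the macrophage gene Adgre1 from −0.002 to 0.43. The floor of 3 counts is at most 0.0286 CPM per library, and Cdkn2a was the named gene with too few counts to be tested.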

Other observations

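Ribosomal protein genes and the neighbours of Zfp36l1 were chosen for a look after their values were seen, as was the test of short genes. The tests of linked segments and of other splits were set beforehand. The other tests of ribosomal protein genes were set before their own results, but for genes chosen after their values were seen. Of 75 tested ribosomal protein genes 19 fell, 0 rose and 56 did not pass by edgeR's quasi-likelihood test, and they were not tested as a list. All 75 had a log2 fold change below 0 under TMM, with a median of −0.30 (quartiles −0.33 and −0.25). They took 0.75%, 0.743%, 0.628% and 0.737% of counts in control libraries 1 to 4 and 0.528%, 0.528%, 0.519% and 0.552% in knockout libraries 1 to 4. The TMM-scaled score, their mean log2 CPM relative to the control mean, was 0.10, 0.04, −0.23 and 0.09 in control and −0.29, −0.27, −0.36 and −0.25 in knockout libraries, so control library 3 lies next to the knockout libraries. The median was −0.42 with total counts alone (65 genes lower), −0.29 with DESeq2 size factors (18 lower) and −0.30 with the replicate block (40 lower). Loss of short transcripts is argued against by 215 genes matched on length and expression, whose median was 0.023. Those genes were longer (median 1057 bases, against 740 for ribosomal protein genes), but the 484 other genes of at most 740 bases had a median log2 fold change of 0.017 (quartiles −0.19 and 0.23). Without the 10 most abundant genes the median of the ribosomal protein genes still differed from that of all genes by −0.292. A larger share of counts on a few abundant genes would lower all other genes alike, so leaving them out could not change this difference. That step decides nothing about such a share, and the value shows only that ribosomal protein genes lay below other genes. A lower level of these mRNAs caused by the deletion stays open as a hypothesis, beside a library batch, which the labels do not give, and an effect of the Cre transgene, neither of which was tested.

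Near Zfp36l1 on chromosome 12, 11 of 152 tested genes within 10 Mb changed (7.2%, against 5.39% of all tested genes). 9430078K24Rik, a long noncoding RNA gene (79917019 to 79936264) on the same strand as Zfp36l1, had 0 counts in all 4 control libraries and 37, 40, 32 and 33 in knockout libraries 1 to 4, at least 42.3-fold higher against a floor of 3 counts over the group (adjusted p = 0.0037). That bound would be smaller if both mates of a read pair were counted. Gene counts do not show whether these reads come from the altered locus. By the labels both groups carry loxP-flanked alleles of Zfp36l1. Strain sequence linked to those alleles would be expected in both groups, which speaks against it as the source, but gene counts cannot test it. It was the only gene at 0 in 1 group with at least 10 counts in each library of the other. 2310015A10Rik (80120546 to 80132844), whose lower coordinate lies 13 kb from that of Zfp36l1, had a log2 fold change of −0.99 (SE 0.22, adjusted p = 0.035, lost in 6 leave-one-out fits). Across the genome, the fullest 10 Mb window of the 171 genes changed at least 2-fold that have an annotated position (Zfp36l1 left out) held 7 of them, on chromosome 19, more than in most random draws (permutation p = 0.0491). A chromosome segment carried by 1 group may account for such a window, but it holds Ifit1, Ifit1bl1, Ifit2 and Ifit3 (higher), Cyp2c39 (higher) and Cyp2c40 and Cyp2c69 (lower), and random draws do not keep neighbouring gene families together.

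Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 801 changed genes, and the highest of the others gave 1. That excludes chance only where libraries can be exchanged across numbers. The 7 other splits that part all 4 same-numbered pairs gave 0 genes by edgeR, and with the real one they are too few for a share under 0.05. All other splits also place the difference between the groups within their own groups, which widens the spread there.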
